A study of Mus musculus with 8 samples.

How the data were processed

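The series holds RNA sequencing of immortalized mouse embryonic fibroblasts, 4 libraries labelled Opa1-/- and 4 labelled Opa1-/- with OPA1 reconstituted. Per the labels' protocols, RNA was extracted with the RNeasy Plus kit and libraries were made with the NEBNext Ultra II RNA kit. Whether the libraries or the counting kept strand is not given in the sources used here, so reads where genes on opposite strands overlap cannot be separated. Per the submitters' processing notes, bcl2fastq 2.17, STAR 2.5.2b, featureCounts and Subread 1.5.2 were used, and the builds mm10 and GRCh38 are named with no role given. The gene identifiers are all mouse. The authors deposited, per the file headers, TPM values with a gene identifier and a name for 49315 genes per library, and each file sums to 1000000 TPM.

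The design written before the data were examined had assumed counts and a quasi-likelihood count test. As the files hold TPM, a count test was not used, and limma-trend on log2(TPM + 1) took its place with the same groups and no covariates. Gene positions, exon lengths and GC content were taken from GENCODE M21 (GRCm38, the assembly of mm10), which held 49056 of the 49315 identifiers. A RefSeq table of GRCm38.p6 gave 4 list members their names in the files. In the files 174 genes have no name.

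TPM keeps no depth of its own. Since TPM times exon length steps in whole multiples of what 1 read is worth, reads were recovered from the low values. Between 92.5% and 93.0% of them were whole within 0.05 of a read. This gave 52.9 M to 57.8 M assigned reads per library (M, 1000000 reads), an estimate that depends on the annotation used here. At that depth a gene at 1 TPM rests on many reads, and the error is set by the spread between libraries. 4 small and ribosomal RNA genes (Gm23935, Gm24270, Gm42418 and Mir6236) took 5.29% to 15.5% of the TPM and 0.338% to 1.21% of the recovered reads. Their share of TPM was lowest, within each group, in both libraries numbered 3, and this moves the TPM of all other genes in a library.

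To remove such shifts, libraries were scaled by a trimmed mean of log ratios (30% of ratios and 5% of levels trimmed at each end, without weights). Genes at 1 TPM or more in at least 4 libraries were tested, 14272 in all. The model was fitted in limma 3.58.1 (R 4.3.3) with a mean-variance trend, two-sided, and p-values were adjusted by Benjamini-Hochberg. A gene was called at adjusted p below 0.05. Scaled TPM are given as mean ± SD. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

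The procedure was tested on simulated libraries made from the means of this comparison with 14251 genes tested and 50 genes changed at each of 4 fold sizes. It recovered 34% of genes changed 1.25-fold, 90% at 1.5-fold and 100% at 2-fold and 4-fold, and 15 of 179 calls (8.38%) were false. A list of 25 other genes raised 1.2-fold gave 2 of the calls. A raised list was found and an unchanged list was not. The simulated genes were drawn independently of each other. The list test was therefore not tried at correlations such as the 0.72 estimated here for mitochondrial DNA-encoded transcripts.

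Gene lists, 29 in number, were fixed before the data were examined. The 25 with at least 5 measured members were tested against all other genes with camera at a preset correlation of 0.01, adjusted over the 25. Named genes followed a rule fixed at the same time. They are Opa1, 13 subject genes, the 10 highest and 10 lowest changes among called genes whose libraries did not overlap and whose mean reached 10 in the higher group, and up to 4 called members of each list with the largest change, plus the most abundant member of each list of cell type markers. Names of the form Gm with digits, ending in Rik or holding -ps were left out of the largest changes. The rule gave the minimum in CPM, and TPM was used. Other genes, named because few members of a list moved against it or as single cases, were chosen after their values were seen.

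No pair of libraries agreed within sampling noise. The lowest chi-square per degree of freedom on recovered reads was 4.75, between reconstituted libraries 1 and 2, so all 8 were kept as separate samples. Alternatives fixed before the data were examined, for counts, were other scalings, other filters, limma-voom, the replicate number as a block, mitochondrial genes left out, each library left out, a test against a 2-fold change, and other list tests. Once the unit was known they were carried over to TPM, and limma-voom and the CPM filter to the recovered reads. Added after seeing the data were TPM as deposited, a pseudocount of 0.1, chromosome medians removed, both libraries numbered 3 left out, protein-coding genes only, and each library's trend with exon length and GC content removed by natural splines with 4 degrees of freedom each.

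Chromosome medians used 9416 genes with a mean log2 value above 3. For the exact test, each library's values were centred on the mean of all 8 libraries. To look for nuclear copies of mitochondrial genes, words of 50 bases from each mitochondrial mRNA were searched in the annotated nuclear transcripts. Copies outside annotated transcripts are not seen this way.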

Results

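RNA sequencing was done on immortalized mouse embryonic fibroblasts (MEFs) of 2 kinds, cells labelled Opa1-/- and Opa1-/- cells into which OPA1 had been put back, with 4 libraries of each. OPA1 is a dynamin-like GTPase of the mitochondrial inner membrane that fuses inner membranes and shapes cristae. The study asked how loss of OPA1 changes the transcriptome, with genes tied to ferroptosis, an iron-dependent cell death driven by lipid peroxidation, as its stated subject. Each deposited file listed TPM (transcripts-per-million) values for 49315 genes, of which 14014 to 14551 were at 1 TPM or more. The depth implied by the TPM steps was 52.9 M to 57.8 M assigned reads per library (M, 1000000 reads). All differences below are knockout-labelled minus reconstituted libraries, as log2 of scaled TPM plus 1, which understates the change of low genes. Means are scaled TPM ± SD with n = 4 libraries per group. Adjusted p-values are from limma-trend with Benjamini-Hochberg adjustment over 14272 genes. The labels do not say that the libraries came from separate cultures, so these p-values measure only the spread between these libraries, which may be technical. Genes named only because few members of a list moved against it were chosen after their values were seen.

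Opa1 itself (ENSMUSG00000038084; GRCm38 chromosome 16, 29579334 to 29654884, plus strand, protein-coding) was at 14.8, 14.7, 13.7 and 12.5 TPM in knockout-labelled libraries 1 to 4. Reconstituted libraries 1 to 4 were at 15.6, 14.6, 14.5 and 14.5 TPM. The difference was -0.09 (SE 0.06, 95% confidence interval -0.22 to 0.05, adjusted p = 0.306), so the total for the gene did not separate the groups and does not check the labels. Values per exon were not analysed here, and a disrupted allele that is still transcribed, or an added OPA1 sequence whose reads are not assigned to the mouse gene, would not be seen in this total. Group names below are therefore those of the labels.

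Between the groups, 4714 of 14272 genes passed adjusted p below 0.05, of which 2322 were higher and 2392 lower in the knockout-labelled libraries. Changes were mostly small, with 122 genes at least 2-fold higher and 58 at least 2-fold lower. The number of 2-fold genes depended on the scale. With a pseudocount of 0.1 TPM it was 266 higher and 103 lower, with limma-voom on reads recovered from the TPM it was 270 and 111, and in a test against a 2-fold change itself (limma treat) it was 10 and 6. On the deposited TPM without scaling, 1752 genes were higher and 1529 lower, against 2322 and 2392.

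**Figure D1:**
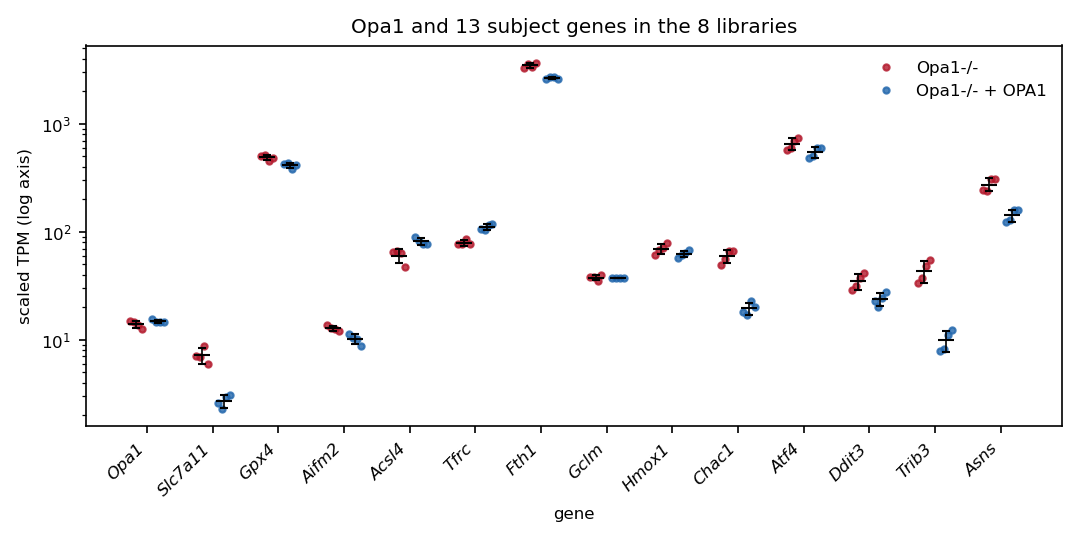
Scaled TPM (log axis) of Opa1 and the 13 subject genes in each library, as points, with group mean and SD as black bars (n = 4 per group). Chac1 lay at 59.7 ± 8.39 TPM in the knockout-labelled libraries and 19.6 ± 2.55 in the reconstituted libraries, while the Opa1 values of the groups overlapped.

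Targets of the integrated stress response, the program that follows phosphorylation of eIF2-alpha and runs through the transcription factor ATF4, were higher in the knockout-labelled libraries. Of 30 measured members, 24 rose, 2 fell (Tnfrsf10b and Ankrd1) and 4 did not pass, and 26 rose and 2 fell when adjusted over the list alone. Trib3, a pseudokinase, was at 43.4 ± 9.71 against 9.90 ± 2.16 TPM (2.02, SE 0.18, adjusted p = 7.69e-05), and Chac1, a glutathione-degrading enzyme, rose by 1.56 (SE 0.11, adjusted p = 3.72e-05). Vldlr, a lipoprotein receptor, rose from 6.56 to 19.7 TPM and Asns, asparagine synthetase, from 142 to 274 TPM. Ddit3, encoding CHOP, was at 34.8 ± 5.68 against 23.7 ± 3.19 TPM (0.53, adjusted p = 0.0105). A short stretch at its 3' end overlaps Mars on the opposite strand, and counting by strand is not stated, so reads within that stretch cannot be separated. Without both libraries numbered 3 the adjusted p of Ddit3 was 0.0538. Atf4 was at 655 ± 77.4 against 545 ± 61.1 TPM (0.26, SE 0.10, adjusted p = 0.0731). In knockout-labelled libraries 1 to 4 Atf4 was at 578, 604, 694 and 744 TPM, and in reconstituted libraries 1 to 4 at 484, 502, 594 and 602 TPM. Libraries 3 and 4 were thus higher than 1 and 2 in both groups. It passed at 0.0452 without knockout-labelled library 1, at 0.0483 over protein-coding genes only and at 0.0496 with a filter of 1 CPM on recovered reads. As a list, these genes were higher than the other genes tested (camera, adjusted p = 9.73e-12), and adjusted p = 0.244 with an estimated correlation.

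Genes of amino acid supply were also mostly higher among those that passed. Among 23 measured genes of serine, one-carbon and non-essential amino acid synthesis, 13 rose and 4 fell (Shmt1, Mthfd1, Got2 and Glul), the same counts when adjusted over the list alone. Cth, cystathionine gamma-lyase, which makes cysteine, rose from 8.78 ± 0.705 to 32.9 ± 5.70 TPM. Aldh1l2 rose from 13.6 to 39.7 TPM, Psph from 18.6 to 48.0 TPM and Pck2 from 36.5 to 80.8 TPM. The list test gave adjusted p = 0.020 (camera), 0.443 with an estimated correlation and 0.108 once genes shared with the stress response list were left out. Cytosolic aminoacyl-tRNA synthetases had 10 of 20 members higher and 2 lower (Farsa and Kars), with the same counts when adjusted over the list alone, and Cars, Lars, Sars and Mars rose by 0.56, 0.50, 0.48 and 0.47. Their list test gave adjusted p = 0.0210 (camera), 0.551 with an estimated correlation, and 0.0572 without knockout-labelled library 3. Amino acid transporters had 8 of 18 members higher and 4 lower, 9 and 4 when adjusted over the list alone, and did not pass as a list (adjusted p = 0.109). Slc7a3, a cationic amino acid transporter on the X chromosome, rose from 11.1 to 36.1 TPM, Slc1a4 from 9.79 to 20.5 TPM and Slc6a9 from 7.50 to 12.5 TPM.

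Of the genes listed beforehand as restraining ferroptosis, 15 of 37 measured rose and 4 fell (Gss, Dhodh, Mboat1 and Sephs2). These counts were 17 and 5 when adjusted over the list alone. Slc7a11, the cystine importer of system xc- (chromosome 3, 49892526 to 50443614, minus strand), was at 7.17 ± 1.15 against 2.73 ± 0.371 TPM (1.13, SE 0.11, adjusted p = 0.000162). Gpx4, the glutathione peroxidase that reduces lipid hydroperoxides (chromosome 10, 80047166 to 80056439, plus strand), was at 489 ± 26.6 against 413 ± 20.4 TPM (0.24, SE 0.05, adjusted p = 0.00741), and at 0.14 (adjusted p = 0.0148) with each library's trend with exon length and GC content removed. Aifm2, which encodes the ubiquinone reductase FSP1, rose by 0.30 (SE 0.08, adjusted p = 0.0144), with adjusted p = 0.0598 without both libraries numbered 3. Hspb1, a small heat shock protein, rose from 6.24 to 15.2 TPM, and Ftl1, a ferritin subunit, from 565 to 818 TPM. The list gave adjusted p = 0.0159 (camera) and 0.267 with an estimated correlation.

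Genes listed beforehand as promoters or markers of ferroptosis went both ways, with 6 of 28 higher and 10 lower, 7 and 11 when adjusted over the list alone. The list did not pass (camera, adjusted p = 0.616, median -0.02). Acsl4, which loads polyunsaturated fatty acids into lipids (X chromosome, 142317993 to 142390535, minus strand), was at 60.2 ± 8.54 against 81.6 ± 5.57 TPM (-0.44, SE 0.10, adjusted p = 0.00948). The median over 301 X-linked genes was -0.36, and with each chromosome's median removed Acsl4 was at -0.10 with adjusted p = 0.510. Sat1 and Tmem164, named after their values were seen, are also X-linked and fell by 0.36 and 0.42. With that median removed they were at -0.01 (adjusted p = 0.892) and -0.08 (adjusted p = 0.466). Tfrc, the transferrin receptor, fell from 111 to 79.1 TPM (-0.48, adjusted p = 0.000371), and Ptgs2, a prostaglandin synthase, from 237 to 155 TPM. The same list holds Chac1, which rose.

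Glutathione genes had 16 of 25 members higher and 2 lower (Gss and Gpx8), 17 and 3 when adjusted over the list alone, with adjusted p = 1.81e-05 (camera) and 0.267 with an estimated correlation. Mgst1, a membrane glutathione transferase, rose from 1.62 ± 0.229 to 8.71 ± 1.58 TPM, and Gsta4 from 25.3 to 62.2 TPM. Gclm, the modifier subunit of glutamate-cysteine ligase, did not pass (37.5 ± 2.02 against 37.5 ± 0.167 TPM). Targets of NRF2, the transcription factor of the oxidative stress response, had 15 of 30 members higher and 1 lower, 16 and 2 when adjusted over the list alone (camera, adjusted p = 2.28e-05, and 0.244 with an estimated correlation). The lower one, the X-linked G6pdx, was at -0.25 (adjusted p = 0.000810), and with each chromosome's median removed at 0.10 (adjusted p = 0.0805). Gstm1 rose from 39.0 to 76.6 TPM. Hmox1 did not pass (0.16, SE 0.08, adjusted p = 0.160), and with each chromosome's median removed it was at 0.34 with adjusted p = 0.0143. Iron handling genes went both ways, with 10 of 28 higher and 6 lower, 10 and 7 when adjusted over the list alone (adjusted p = 0.458). Fth1, ferritin heavy chain, was at 3483 ± 172 against 2669 ± 52.2 TPM (0.38, SE 0.05, adjusted p = 0.000541). Slc40a1, the iron exporter, and Bdh2 rose from low levels, 0.390 to 1.16 TPM and 0.882 to 1.62 TPM.

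**Figure D2:**
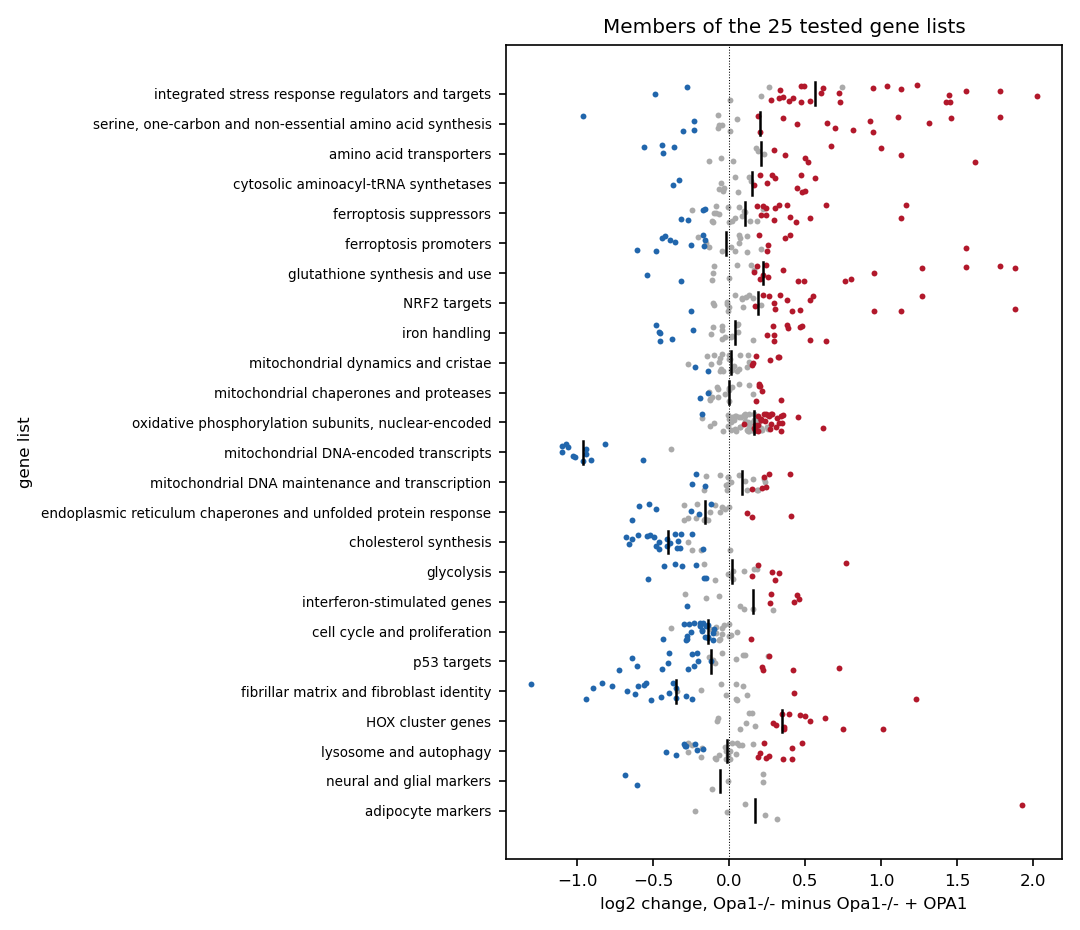
Log2 change (knockout-labelled minus reconstituted libraries) of each measured member of the 25 tested lists, with the list median as a black line (red, higher and blue, lower at adjusted p below 0.05; grey, not passing). The medians ran from -0.97 for mitochondrial DNA-encoded transcripts to 0.57 for the integrated stress response.

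Transcripts encoded by mitochondrial DNA were lower in the knockout-labelled libraries. They took 2.67% to 3.35% of the TPM there and 5.33% to 5.77% in the reconstituted libraries. Of the 13 mRNAs, 12 fell, also when adjusted over the list alone, with a median of -0.97 (camera, adjusted p = 3.51e-08, and 0.325 with an estimated correlation). mt-Nd5 was at 1766 ± 246 against 3699.7 ± 83.2 TPM (-1.08, adjusted p = 5.83e-05). mt-Cytb was at 4246 against 8519 TPM, and mt-Nd6, on the opposite strand, was at 1549 against 3133 TPM, both chosen after their values were seen. As counting by strand is not stated, reads of the other strand over mt-Nd6 cannot be separated from its own. Its value therefore does not show that transcripts of both strands fell. The mRNA that did not pass was mt-Nd3 (4.76 against 5.58 TPM). mt-Co2, mt-Atp6 and mt-Atp8 were listed at only 8.68, 7.53 and 10.4 TPM against 19.4, 16.9 and 22.1 TPM. Of the words of 50 bases in mt-Co2, mt-Co3, mt-Atp6, mt-Nd4l and mt-Nd3, 98.0% to 100% recur in annotated nuclear transcripts, and 62.2% of those in mt-Nd4 and 51.1% in mt-Co1, so these values are uncertain. The word search found none for mt-Atp8 in annotated transcripts, and its value is treated as uncertain because its level was as low.

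Nuclear-encoded subunits of oxidative phosphorylation moved the other way by small amounts, with 29 of 74 higher and 1 lower, 36 and 1 when adjusted over the list alone (median 0.17; camera, adjusted p = 8.00e-07, and 0.544 with an estimated correlation). The lower one, the X-linked Ndufb11, was at -0.18 (adjusted p = 0.0421), and with each chromosome's median removed at 0.16 (adjusted p = 0.0724). Without knockout-labelled library 4 the median was 0.11. Uqcrq rose from 153 to 236 TPM, Ndufs6 from 195 to 268 TPM and Ndufb9 from 332 to 425 TPM. Ndufa6 was at 337 against 262 TPM (adjusted p = 0.0227), and at 0.0574 and 0.0581 without reconstituted library 1 and 2, and at 0.0607 with no filter on low values. These genes are short, with a median exon length of 1778.5 bases against 3709.5 for all genes tested. Glutathione genes were also short, with a median of 1813 bases. The difference between the groups itself ran along gene length (Spearman rho across 9416 genes -0.21). Knockout-labelled library 4 differed from the other knockout-labelled libraries along gene length (rho -0.46), and libraries 3 and 1 differed in the other direction (0.47 and 0.35). Genes are not independent replicates. Genes of mitochondrial dynamics and cristae had 6 of 30 higher and 2 lower, 6 and 1 when adjusted over the list alone (adjusted p = 0.562). 2410015M20Rik (Mic13), of the cristae junction complex, rose by 0.33, Mief2 by 0.32 and Fis1 by 0.27, and Mfn1 fell by 0.23. The Mfn1 call was lost without reconstituted library 3 (0.0565) or 4 (0.0544), and on the deposited TPM (0.103). Mitochondrial chaperones and proteases had 6 of 23 higher and 2 lower, 6 and 3 when adjusted over the list alone (adjusted p = 0.616, with a median of -0.00 and a mean of 0.03). Lonp1 rose from 153 to 194 TPM, Hspa9 from 832 to 953 TPM and Trap1 from 104 to 121 TPM, with adjusted p = 0.0740 for Hspa9 and 0.0609 for Trap1 on the deposited TPM. Pmpcb rose by 0.20, and with each chromosome's median removed it was at 0.14 with adjusted p = 0.0753. Genes of mitochondrial DNA maintenance had 6 of 26 higher and 3 lower, 7 and 5 when adjusted over the list alone (adjusted p = 0.303), and Mpv17 rose from 37.6 to 49.9 TPM. Mgme1 rose by 0.24 (adjusted p = 0.0617 on the deposited TPM). Ssbp1 was at 30.1 against 24.8 TPM (adjusted p = 0.0273), and without knockout-labelled library 2 or reconstituted library 1, 3 or 4 at 0.0652, 0.0621, 0.0721 and 0.0593, and at 0.0617 with no filter on low values. Lig3 was at 20.4 against 24.3 TPM (adjusted p = 0.0400), and did not pass when any of 6 libraries was left out, with no filter on low values (0.0862), with upper-quartile scaling (0.0537) or on the deposited TPM (0.141). It was at 0.0723, 0.0894 and 0.0536 without knockout-labelled library 1, 2 and 4 and at 0.0827, 0.107 and 0.0846 without reconstituted library 1, 3 and 4.

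Cholesterol synthesis genes were lower, with 20 of 24 members below and none above, 23 and 0 when adjusted over the list alone (median -0.40; camera, adjusted p = 1.00e-09, and 0.267 with an estimated correlation). Msmo1 fell from 101 ± 1.08 to 63.4 ± 5.30 TPM and Idi1 from 70.0 to 45.4 TPM. Nsdhl and Ebp, both X-linked, fell by 0.68 and 0.60, and with each chromosome's median removed they were at -0.34 (adjusted p = 0.0221) and -0.26 (adjusted p = 0.00932). Endoplasmic reticulum chaperones and unfolded protein response genes had 3 of 24 higher and 7 lower, the same when adjusted over the list alone (camera, adjusted p = 0.0104, and 0.517 with an estimated correlation). Calr fell from 839 to 559 TPM, Pdia6 from 325 to 225 TPM, and Dnajc3 from 23.9 to 16.9 TPM (-0.49, and -0.32 with each chromosome's median removed). Eif2ak3, which encodes the eIF2-alpha kinase PERK, fell by 0.64.

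Matrix and fibroblast genes had 18 of 29 members lower and 2 higher, the same when adjusted over the list alone (camera, adjusted p = 3.02e-05, and 0.325 with an estimated correlation). Tnc, tenascin C, fell from 82.6 to 32.9 TPM, Ctgf from 115 to 59.4 TPM and Col6a3 from 13.1 to 6.65 TPM, while Thbs2 rose from 4.88 to 12.8 TPM. Cell cycle genes fell by small amounts, 21 of 36 lower and 1 higher (Ccnb2), 23 and 1 when adjusted over the list alone (median -0.14; camera, adjusted p = 2.29e-06, and 0.115 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, fell from 285 to 210 TPM, Ccna2 from 187 to 154 TPM and Cenpe from 49.8 to 40.7 TPM. Mcm5 fell by 0.30, and with each chromosome's median removed it was at -0.11 with adjusted p = 0.0918. HOX cluster genes, which keep positional identity, had 12 of 19 higher and 0 lower, also when adjusted over the list alone (median 0.35; camera, adjusted p = 1.57e-05, and 0.382 with an estimated correlation). Hoxa11 rose from 32.2 to 54.8 TPM, Hoxa9 from 23.7 to 37.3 TPM and Hoxb8 from 18.6 to 27.3 TPM. Hoxb13 rose from a low level, 0.349 to 1.71 TPM.

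The remaining pathway lists did not pass. Targets of p53 had 5 of 25 higher and 12 lower, the same when adjusted over the list alone (adjusted p = 0.0909). They passed at 0.0391 without reconstituted library 1, at 0.0117 with no filter on low values and at 0.0103 with each chromosome's median removed. Plk2 fell from 291 to 177 TPM and Perp from 46.0 to 29.8 TPM, and Sesn2 rose from 17.4 to 29.4 TPM. Fas was at 10.3 against 16.3 TPM (adjusted p = 0.0217), and without knockout-labelled library 1 or 2 or reconstituted library 3 or 4 at 0.0536, 0.0575, 0.0584 and 0.0594. It was at 0.0603 with no filter on low values and at 0.0830 without both libraries numbered 3. Interferon-stimulated genes had 5 of 13 higher and 1 lower, 5 and 2 when adjusted over the list alone (adjusted p = 0.182), and Bst2 rose from 18.8 to 25.5 TPM. Parp9 and Gbp2 rose by 0.46 and 0.45, and Ifit2 fell by 0.28 (adjusted p = 0.0678 without both libraries numbered 3). Glycolysis genes had 6 of 22 higher and 7 lower, 8 and 9 when adjusted over the list alone (adjusted p = 0.908; median 0.02 and mean 0.00 against a test direction of lower). Slc16a3, a lactate transporter, rose from 3.17 to 6.10 TPM, and Pfkfb3 fell by 0.36 (adjusted p = 0.0649 without both libraries numbered 3). The X-linked Pgk1 and Pdk3 fell by 0.43 and 0.54, and with each chromosome's median removed they were at -0.08 (adjusted p = 0.113) and -0.19 (adjusted p = 0.0660). Lysosome and autophagy genes had 9 of 38 higher and 8 lower, 9 and 9 when adjusted over the list alone (adjusted p = 0.832). Hexa rose from 90.8 to 127 TPM, Bnip3 from 23.3 to 31.4 TPM and Calcoco1 from 17.0 to 23.0 TPM. Tfe3, X-linked, fell by 0.42, and with each chromosome's median removed it was at -0.07 with adjusted p = 0.390.

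The largest increases among called genes whose libraries did not overlap and whose mean reached 10 TPM in the higher group were in H19, an imprinted long noncoding RNA (chromosome 7, 142575529 to 142578143, minus strand), at 78.4 ± 28.9 against 14.0 ± 2.36 TPM (2.34, SE 0.24, adjusted p = 0.000182), then Trib3, Cebpa, Adm2, Chchd10, Cth, Penk, Ptchd1, Slc7a3 and S100a16. Cebpa, a transcription factor of adipocyte and myeloid differentiation, rose from 3.23 to 15.1 TPM. Adm2 rose from 9.18 to 36.1 TPM, Chchd10, a protein of the mitochondrial intermembrane space, by 1.82, and Penk, proenkephalin, from 9.37 to 34.7 TPM. S100a16 rose from 3.17 to 11.2 TPM and Ptchd1 from 2.70 to 10.4 TPM. The largest decrease among genes under the same limits was in Acan, the cartilage proteoglycan aggrecan, at 16.3 ± 1.76 against 63.0 ± 2.55 TPM (-1.89, SE 0.07, adjusted p = 2.12e-06). Runx3 fell from 11.7 to 2.51 TPM, Il18rap from 12.6 to 3.32 TPM and Slc14a1, a urea transporter, from 76.0 to 24.7 TPM, and Klra4 fell by 1.69. Esx1, Krt80, Ifitm1, Kcnf1 and Efnb1 fell by 1.43, 1.38, 1.37, 1.35 and 1.34. Ptchd1, Slc7a3, Esx1 and Efnb1 are X-linked. Klra4 belongs to a family of near-identical genes, so its value is uncertain.

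Markers of other cell types were few and did not move one way. Of 4 epithelial markers measured, Krt19 rose from 37.3 ± 2.03 to 95.4 ± 15.8 TPM, Krt8 from 2.20 to 4.61 TPM and Cdh1 from 8.10 to 12.9 TPM, while Krt18, the most abundant, was at 170 ± 16.5 against 165 ± 29.4 TPM and did not pass. Of 3 macrophage and leukocyte markers, Cd14 was lower (43.5 against 54.4 TPM, adjusted p = 0.0332). That call was lost without knockout-labelled library 4 (0.0537) or reconstituted library 1, 2 or 4 (0.0816, 0.0823 and 0.0513), and with no filter on low values (0.0807). With each chromosome's median removed Cd14 was at -0.30, against -0.33, and did not pass (0.0561). Of 2 endothelial markers Egfl7 rose from 4.57 to 6.80 TPM. Of 2 skeletal muscle markers Tnnt3 was higher (2.24 against 1.01 TPM, 0.65, adjusted p = 0.0263), and Acta1 did not pass (4.39 against 3.49 TPM). The Tnnt3 call was lost with no filter on low values (0.0704) and without knockout-labelled library 3 (0.0645). Leaving out reconstituted library 1, 2 or 4 also lost it (0.0573, 0.0501 and 0.0697). With each chromosome's median removed Tnnt3 was at 0.54 (adjusted p = 0.0622), and without both libraries numbered 3 at 0.62 (adjusted p = 0.0964). Of 6 neural and glial markers Nes fell from 56.7 to 35.1 TPM and Tubb3 from 19.3 to 12.4 TPM (list adjusted p = 0.411). Of 6 adipocyte markers only Cebpa passed, and Pparg was at 17.8 against 14.9 TPM (list adjusted p = 0.172). In each of these 6 lists the counts were the same when adjusted over the list alone.

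Gene levels also differed by chromosome, a comparison chosen after the data were seen. Over 301 X-linked genes the median was -0.36, with 91.7% of them lower, and each knockout-labelled library lay between -0.36 and -0.33 against the mean of the reconstituted libraries (two-sided exact permutation test on 8 libraries, p = 0.0286, the smallest that 4 against 4 allows, adjusted p = 0.0409 over 20 chromosomes). Medians were -0.18 on chromosome 8, -0.17 on 14, -0.15 on 4 and -0.10 on 12, and 0.11 on chromosome 7 and 0.10 on 9. The same p was reached on 14 of the 20 chromosomes, down to medians of -0.02 on chromosome 2 and 0.02 on 19, so it does not set the chromosomes named here apart. Of 485 X-linked genes tested, 266 were lower and 23 higher. With each chromosome's median removed, 2180 genes were higher and 1625 lower, and 9 genes were called in the opposite direction.

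**Figure D3:**
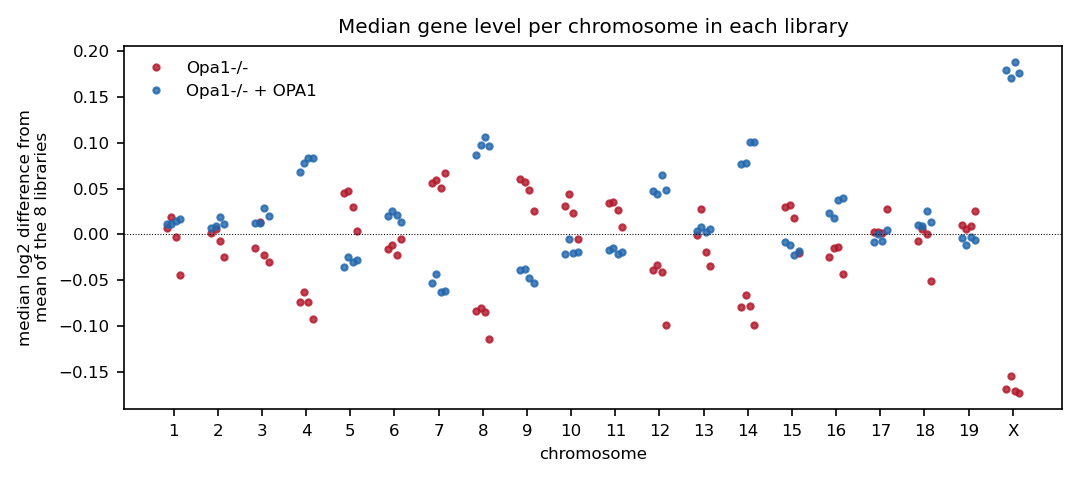
Median log2 difference of each library from the mean of the 8 libraries, over genes with a mean log2 value above 3, for each chromosome. On the X chromosome the knockout-labelled libraries lay between -0.17 and -0.15 and the reconstituted libraries between 0.17 and 0.19.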

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

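The tests of length and GC content on X-linked genes, mitochondrial transcripts and oxidative phosphorylation subunits were set before their results were seen, and the other tests of this part were chosen after.

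Of the 35 splits of the 8 libraries into 4 and 4, 1 (the real split) called as many as 4714 genes, and the highest of the others called 2. Each of the others mixes the groups, so the group difference enters their spread and few calls were to be expected. The calls thus follow the labelled groups. Whether such a count could arise by chance between cultures or lines cannot be decided this way.

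X-linked genes were lower in every knockout-labelled library. Transcript length and GC content are argued against as the whole cause, since the X median was -0.32 after each library's trend was removed. Library 4 alone is argued against by the values already given, with each knockout-labelled library between -0.36 and -0.33. The median of -0.35 without library 4 followed from these and tests nothing further. A lower dose of the whole X chromosome in the knockout-labelled line is a candidate explanation, as the median was -0.26 or lower in all 8 windows of 20 Mb with at least 20 genes. A karyotype was not analysed here, and whether the shift is a response to OPA1 loss or a difference that arose between the lines cannot be told apart with 1 line pair. The same holds for the smaller shifts on chromosomes 4, 7, 8, 9, 12 and 14.

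Mitochondrial DNA-encoded mRNAs were lower along the molecule, from -1.10 for mt-Co2 to -0.38 for mt-Nd3, which did not pass, and both of these are uncertain as nearly all their sequence recurs in nuclear transcripts. Reads shared with nuclear copies are argued against as the cause, since the 6 mRNAs with under 10% of their words in annotated nuclear transcripts had a median of -1.02. These 6 include mt-Atp8 (-1.06), whose value is treated as uncertain above. The others, mt-Nd1, mt-Nd2, mt-Nd5, mt-Nd6 and mt-Cytb, ran from -1.08 to -0.82. Length and GC content are also argued against, as the median of the 13 was -0.95 after the trend was removed. Less mitochondrial DNA or less transcription of the whole molecule stays open, since the count of 13 of 13 below -0.2 followed from the 12 already called lower and tests nothing further. Mitochondrial DNA was not measured, and a difference between the lines unrelated to OPA1 was not tested.

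The rise of nuclear-encoded oxidative phosphorylation subunits, which are short, is less settled. Their median of 0.17 was 0.13 after the length and GC trend was removed, with 0.07 to 0.20 across the knockout-labelled libraries, and 0.11 without library 4, with 0.05 to 0.21. Both medians stayed above the bound of 0.1 that had been set for them. The lowest knockout-labelled library lay below it each time, so these explanations are not taken as excluded. Part of the rise may therefore come from transcript length or from library 4, in which short genes were highest. No biological explanation was tested.

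Knockout-labelled library 4 stood apart from the other knockout-labelled libraries over many genes. On the second principal component it was at -25.5 against 4.71 to 12.98, and its chi-square per degree of freedom against them was 33.7 to 47.9, against 7.89 to 24.5 among them. The SD over 9416 genes of its log2 difference from the mean of the other 3 was 0.24, against 0.14 to 0.15 for those. It was kept, and without it 2572 genes were higher and 2731 lower. The cause was not tested.

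A library far from the other 3 of its group was found in 7 of 244 groups of values of single genes or library measures, fewer than the 1 in 20 that chance gives. For Opa1, reconstituted library 1 was at 15.6 TPM against 14.5 to 14.6 in the others (gap over range 0.956). For Acsl4, knockout-labelled library 4 was at 47.5 against 63.2 to 65.8 TPM (0.875), and for Vldlr the same library was at 16.4 against 20.4 to 21.2 TPM (0.86). For Tfrc, knockout-labelled library 3 was at 86.1 against 76.6 to 77.3 TPM (0.92). For Ctgf, knockout-labelled library 1 was at 55.2 against 60.7 to 61.1 TPM (0.936). The TPM share of 4 small and ribosomal RNA genes was low in both libraries numbered 3, 10.96% against 14.9% to 15.5% (0.868) and 5.29% against 13.6% to 14.2% (0.931).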

How the results depend on the processing

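Alternatives chosen after the data were seen were the deposited TPM, the pseudocount of 0.1, chromosome medians removed, both libraries numbered 3 left out, protein-coding genes only, list tests on limma-voom values, and the length and GC trend removed. Opa1 did not pass in any of 21 alternatives (-0.11 to -0.01). Leaving out each library in turn gave 1726 to 2572 genes higher and 1795 to 2731 lower. In the scalings tried, the share of higher calls was 49.3% to 57.4%, and no gene called both in the reported fit and in an alternative changed direction, except 9 with chromosome medians removed. Genes at least 2-fold higher and lower were 270 and 111 with limma-voom, 266 and 103 with a pseudocount of 0.1, and 10 and 6 in a test against a 2-fold change. Without scaling, 1752 genes were higher and 1529 lower. A smaller pseudocount shrinks low genes less and the test against 2-fold asks for more, both by construction, and the cause of the limma-voom counts was not tested.

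With a correlation estimated per list, 0 lists were called by camera, against 13 at the preset value. The adjusted p-values were 0.244 for the stress response, 0.443 for serine and one-carbon genes, 0.551 for tRNA synthetases, 0.267 for ferroptosis suppressors, glutathione and cholesterol, 0.244 for NRF2, 0.544 for oxidative phosphorylation, 0.325 for mitochondrial DNA transcripts and matrix, 0.517 for the endoplasmic reticulum, 0.115 for the cell cycle and 0.382 for HOX genes. With fry, tRNA synthetases were at 0.0501, and iron handling (0.00370), mitochondrial DNA maintenance (0.0438), interferon-stimulated genes (0.00483), p53 targets (0.00403), neural markers (0.0492) and adipocyte markers (0.000669) passed. fry does not compare a list with other genes. With stress response members left out, serine genes were at 0.108 and p53 targets at 0.0157. With no filter, amino acid transporters (0.0198), p53 targets (0.0117) and adipocyte markers (0.00776) passed. With chromosome medians removed, p53 targets were at 0.0103. Leaving out a library gave 0.00906 to 0.0572 for tRNA synthetases and 0.0391 to 0.122 for p53 targets. Glycolysis, never passing, turned direction on deposited TPM (0.926) and without knockout-labelled library 4 (0.674), with 0.674 to 0.980 over libraries left out. Lysosome genes turned with chromosome medians removed (0.307) and without knockout-labelled library 4 (0.958), with 0.714 to 0.958 over libraries left out. Unless stated, the cause was not tested.

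Of 117 named genes besides Opa1, 111 were called, none of which changed direction, and 20 lost their call in at least 1 alternative. Gclm and Krt18, not called, changed sign. Gclm was at 0.03 with upper-quartile scaling (0.0283), chromosome medians removed (0.0296) and both libraries numbered 3 left out (0.0349), at 0.0658 with the length and GC trend removed, and between -0.0272 (without knockout-labelled library 4) and 0.0327 (without knockout-labelled library 3) with a library left out. Krt18 was at -0.0293 with that trend removed, and between -0.0427 and 0.138 with a library left out, below 0 without knockout-labelled library 4 or reconstituted library 3 or 4.

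Over all tested genes, deviations from the group means correlated at 0.05, 0.10, 0.14 and 0.01 between same-numbered libraries. All were positive, and pairs with different numbers ran from -0.15 to 0.06. A weak link between same-numbered libraries is therefore not excluded. Libraries 3 and 4 were also higher than 1 and 2 in both groups for several named genes. Among them were Atf4, Asns, Trib3, Chac1, Ddit3, Cth and H19. The cause of that shared difference was not tested. The replicate block gave 2362 genes higher and 2395 lower, and passed Atf4 (0.00322), Hmox1 (0.0241) and Pparg (0.0229). The planned count tests (the quasi-likelihood fit with its filter and the Wald test) were not run, as the files hold TPM and the recovered reads are estimates, and treat took the place of the planned fold test. The estimated depth was 52.9 M to 57.8 M reads, and its effect on the calls was not tested. In the self-test small changes were missed more often, with 34% of the smallest recovered. It changed far fewer genes than were called here and used 1 fixed dispersion, so its rates need not carry over to these data.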

Other observations

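The values and tests of this part were all chosen after the data were seen. Of 9 Y-linked genes tested, 4 were higher in the knockout-labelled libraries and 5 did not pass, and no test of the group was made. The 4 higher genes lie between positions 897788 and 1286629. Gm29650, also there, was at 0.49 and did not pass (limma-trend adjusted p = 0.0549). The other genes that did not pass lie between 90753057 and 90844040. Ddx3y was at 16.7 ± 1.93 against 10.6 ± 0.809 TPM (0.60, limma-trend adjusted p = 0.000880) and Eif2s3y at 20.7 ± 2.19 against 13.1 ± 1.13 TPM (0.62, adjusted p = 0.000774). Kdm5d and Uty rose by 0.28 and 0.34. Ligands of the immune receptor NKG2D rose from low levels, with Raet1e at 3.72 against 0.683 TPM, Raet1d at 3.04 against 0.499 TPM and H60b at 2.62 against 0.362 TPM, while Ulbp1 fell by 0.55. Raet1e spans the positions of Raet1d and H60b on the same strand, so these 3 can share reads and their values are uncertain. The hypothesis that these ligands are higher as a class was not tested, since 4 were measured and lists of fewer than 5 were left out of the list tests.

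YAP and SRF are regulators of transcription that respond to cell tension. The fall of Ctgf and of matrix genes led to the hypothesis that target genes of YAP and SRF are lower as a class. Of 35 measured, 18 fell and 3 rose, with a median of -0.26. The list was lower than other genes (camera, adjusted p = 4.03e-05 over the 2 lists tested, and 0.0554 with an estimated correlation). Thbs1, Cyr61, Cnn1 and Ajuba fell by 0.77, 0.89, 0.81 and 0.59, and Fjx1, Myl9 and F3 rose by 0.69, 0.38 and 0.27. Ctgf had been seen before the list was written. The list also shares Thbs1, Acta2 and Tagln with the matrix list and Ankrd1 with the stress response list, both already tested. Its p-value is therefore not independent support, and this remains a hypothesis.

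The large change of H19 led to the hypothesis that imprinted genes are higher as a class. Of 31 measured, 10 rose and 3 fell (Nnat, Peg13 and Slc38a4), and the list did not pass (adjusted p = 0.132). Mest, Cdkn1c and Ppp1r9a rose by 0.81, 0.87 and 0.89.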
